A study of Mus musculus with 4 samples.

How the data were processed

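DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in CGR8 cells, a mouse embryonic stem cell line kept in serum with LIF. In RRBS the enzyme MspI cuts DNA at CCGG sites, short fragments are selected on a gel, and bisulfite converts unmethylated cytosines, so that the reads come mostly from CpG-rich parts of the genome. Per the labels' protocols, the cells were stably transfected with an empty expression vector (control, 2 libraries) or with the same kind of vector carrying a netrin-1 transgene (netrin-1, 2 libraries), and libraries were sequenced as read pairs on an Illumina HiSeq. The group and the replicate number of each library came from its title. The labels do not say whether the replicates were separate transfections, clones, cultures or DNA preparations, so the spread between these libraries may be technical. The main p-values do not rest on that spread alone. Those of single features also draw on the dispersion of the other features of the same table. The main test of gene lists judges a list by the variation across promoters.

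The submitters' processing notes name the builds mm10 and GRCm38 and the tool FastQC. The aligner, the methylation caller, filters on sites, the treatment of duplicate reads and the conversion rate are not given in the sources used here. The authors deposited 3 tables, for windows of 100 kb, for CpG islands with their shores and shelves, and for genes. Per the file headers, each table gives for every library the number of covered positions, the count of total calls and the count of methylated calls of each feature, and the methylation level as a fraction. The deposited fraction equalled methylated over total calls within 5.55e-16 and was recomputed as a percent. The same 4 libraries' values in re-sorted or working copies of the tables were not used here. No pair of libraries had identical calls. The window table does not hold every island position. In 54.6% of the 8465 windows that contain an island, the islands listed more covered positions than the window, in the library control 1. Windows and islands are therefore partly separate data, and the rule by which the window table was made is not given in the sources used here. In the gene table each gene has a promoter, reaching 500 bp to either side of the transcription start site, and a gene body.

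Depth in the window table was 28004487 and 37394424 calls in the controls and 32770000 and 44642064 calls in the netrin-1 libraries, or 16.1, 20.4, 18.6 and 23.8 calls per covered position. The median feature with calls held 689 to 1090 calls per library among windows, 220 to 375 among CpG island features and 490 to 847 among gene features. Calls from PCR-amplified reads without molecular identifiers are not independent molecules, so upper limits for groups at 0% (3 calls of the group's total) cover counting error only.

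Mean levels were unweighted means over the features with a value in all 4 libraries, given as mean ± SD over the 2 libraries of a group. They were compared by an exact two-sided permutation test, whose smallest possible p is 0.333 with 2 libraries against 2, so this test cannot reach 0.05. Single features were tested on their counts with a quasi-binomial logistic model. Features had at least 10 calls in every library and levels that were not identical in all 4. The dispersion of each feature was moderated across the features of its table with limma 3.58.1 (a trend on coverage, robust, floor of 1) in R 4.3.3, with the package data.table (version 1.17.8) for reading. Adjusted p-values are Benjamini-Hochberg values over all tested features of the same table, and the threshold was 0.05.

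The groups, the lists, the test family, the threshold, the rule for named features and most alternatives were fixed before the data were examined. The way of estimating the dispersion was not fixed then, and it matters for every count of single features. As first run, with every feature of at least 10 calls tested, the model called 348 windows, 412 CpG island features and 75 gene features. On data simulated at the real coverage this version made many false calls among CpG island features and estimated no spread of dispersion there. After those counts had been seen, 4 treatments were run on the real tables, where they called 248 to 348 windows, 60 to 412 CpG island features and 29 to 114 gene features, and 32 were compared on 3 simulated data sets per table. More than 1 of them kept false calls low, among them a fit that was not robust. An information minimum was then chosen from the simulated results: total calls × level × (1 - level), with the level pooled over the libraries and its proportion taken between 0 and 1, had to average at least 25 per library (100 over the 4 libraries). Features under it were left untested, since they hold little information on their own dispersion. A fit with no minimum and no robust step could also be made, and its counts are given beside the others. All counts are given with this minimum unless stated otherwise. In a fresh simulation with 100 features each lowered by 10 and by 20 percentage points, the test recovered 26 and 73 of 100 windows, 0 and 19 of 100 CpG island features, and 21 and 61 of 100 gene features. The lowered features were taken only from those of intermediate to high level that met the minimum. Recovery at lower levels, where most islands lie, was not simulated. False calls made up 2.94%, 0% and 6.82% of calls in these 3 simulations, which ran on 23709 windows, 11883 CpG island features and 17332 gene features. Unchanged features had the same level in all 4 simulated libraries, without the general fall of the real netrin-1 libraries. These shares therefore need not hold for the real calls.

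The 11 gene lists were tested on promoter levels with limma's camera, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside it stand fry, camera with an estimated correlation, and the percentile of each list's median difference among 10000 random lists matched on level in 20 bins. In simulated promoter data, 3 of 100 unchanged lists had a camera p under 0.05. These were random lists of promoters that varied independently, without the general fall of the real netrin-1 libraries. The simulation therefore does not give the error rate for a list picked for methylated promoters. The lists were naive pluripotency, primed and formative pluripotency, germline genes with methylated promoters, imprinted genes, the netrin pathway, Wnt and MAPK pathway targets, the DNA methylation machinery, two-cell-like genes, three-germ-layer genes, trophoblast genes, and fibroblast genes as markers of another cell type the culture could hold. In all, 7 list genes had no match in the gene table. Gene names are those of the table. Of its 28777 names, 23269 are symbols of the RefSeq annotation of GRCm38.p6, the same build, which was also used for genes overlapping a region.

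The rule for named features took, among promoters past the threshold with groups that do not overlap, the 10 largest rises and 10 largest falls, filled up to 5 with promoters that did not pass where fewer passed. It also took up to 3 members of each list with the largest absolute difference, Ntn1, and likewise 5 windows and 5 CpG island features in each direction. Features named outside it are said to be chosen after their values were seen. A list member that the rule takes is not reported here.

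Coverage was compared in bins of 5 Mb with at least 5000 calls in each library, scaled to the median bin. A bin was set apart where the mean log2 ratio of netrin-1 to control exceeded 0.25 in size and all 4 library pairs had 1 sign. In a simulated table this found 24 of 24 changed bins and 0 false ones. Alternatives covered limma on M values or on percentage points, no moderation, no trend, no information minimum, no robust step, filters on covered positions, calls and level, a minimum difference, centring, the replicate number as a block, leaving out each library, autosomes, weighted means and medians, and leaving out bins of unequal coverage. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.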

Results

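The DNA methylation profiles of mouse embryonic stem cells carrying an empty vector and of cells carrying a netrin-1 transgene were compared by RRBS. Netrin-1 is a secreted, laminin-related protein that signals through receptors such as DCC, neogenin and the UNC5 family. The cells were CGR8 embryonic stem cells grown in serum and LIF, a condition in which such cells express pluripotency genes and keep a methylated genome. There were 2 control and 2 netrin-1 libraries. Control replicates 1 and 2 held 28004487 and 37394424 cytosine calls in 100 kb windows, and netrin-1 replicates 1 and 2 held 32770000 and 44642064. Levels are methylated calls as a percent of all calls, and coordinates are on GRCm38 (mm10).

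The first question was whether the genome as a whole differed in methylation. Methylation was lower in the netrin-1 cells in every class of feature measured. Over 25938 windows of 100 kb the mean level was 38.6% ± 1.18 (SD, n = 2) in control and 34.7% ± 0.637 (SD, n = 2) in netrin-1 cells, a difference of -3.91 percentage points. The lowest control library lay 2.62 points above the highest netrin-1 library, so the gap exceeded the spread within either group. Of the windows, 80.6% had a lower mean level in netrin-1 cells and 19.3% a higher one. Both netrin-1 libraries were below both controls on each of 21 chromosomes. The difference on chromosomes 1 to 19 and X ran from -3.18 points on chromosome 11 to -4.76 points on chromosome 16. The exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 can give. Weighting windows by their calls gave a smaller difference of -2.83 points.

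**Figure D1:**
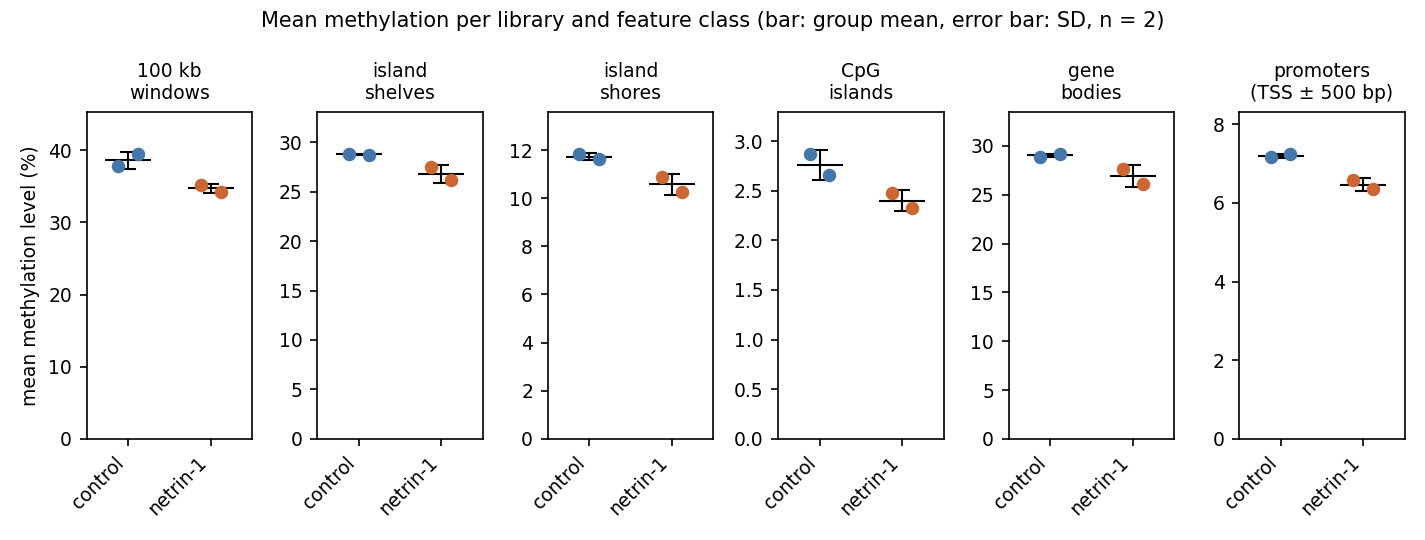
Mean methylation level in percent (vertical axes, from 0) of each library, as points, for 6 classes of feature, with the group mean and its SD (n = 2) as bars. Both netrin-1 libraries lie below both controls in every class, for example at 34.3% and 35.2% against 37.8% and 39.4% in 100 kb windows.

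The difference in points was greatest in windows of low to intermediate methylation. Relative to the control level it was greater at lower levels, at -21.4% in windows of 5 to 10% against -17.0% in those of 20 to 30%. Windows with a mean level of 20 to 30% stood at 28.1% ± 1.10 in control and 23.4% ± 0.646 in netrin-1 cells (SD, n = 2), a difference of -4.78 points. Those of 30 to 40% differed by -4.48 points, those of 40 to 50% by -3.49 points, those of 50 to 60% by -2.37 points and those of 60 to 70% by -1.20 points. In the last of these bins 1 of the library pairs showed no lower level in netrin-1. The few windows above that did not continue the trend: 77 windows of 70 to 80% stood at 75.6% ± 0.00404 and 72.1% ± 0.651, a difference of -3.50 points with groups that did not overlap, and 28 windows of 80 to 100% differed by -1.0 points. At the unmethylated end, 6757 CpG islands with a mean level under 1% stood at 0.658% ± 0.0105 in control and 0.652% ± 0.0496 in netrin-1 cells, a difference within the spread of the netrin-1 libraries.

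**Figure D2:**
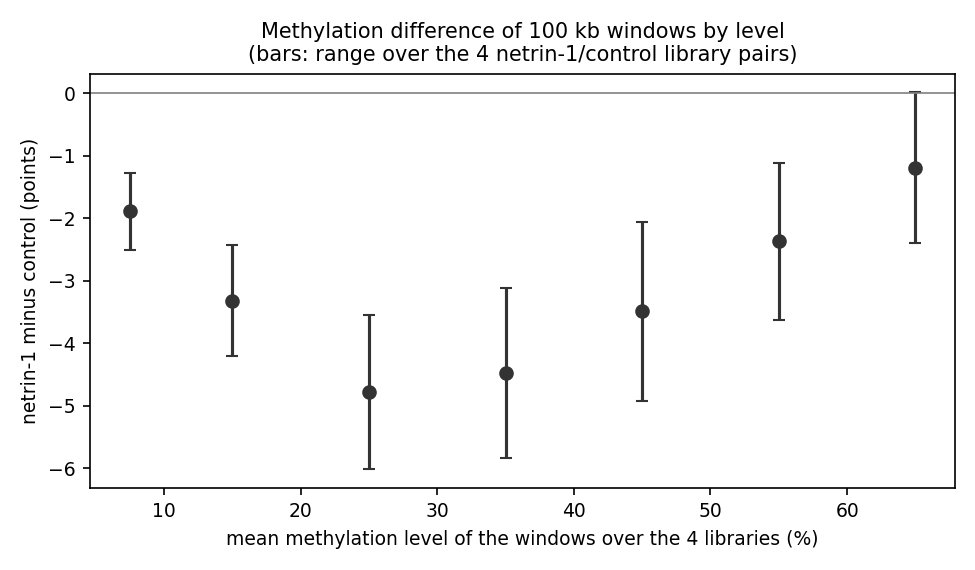
Difference in methylation, netrin-1 minus control in percentage points (vertical axis), of 100 kb windows grouped by their mean level over the 4 libraries in percent (horizontal axis, centre of each bin with at least 100 windows). Points are differences of group means and bars the range over the 4 library pairs. The difference is greatest at 20 to 30%, where it is -4.78 points, and smallest at 60 to 70%, where it is -1.20 points.

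Next, single windows were compared. The moderated quasi-binomial test called 528 of 23743 tested windows, of which 523 fell and 5 rose in netrin-1 cells. The median fall among these was -14.0 points. The 5 greatest falls among windows whose groups do not overlap ran from -29.7 to -30.4 points. A window on chromosome 3 (120500001 to 120600000) fell from 53.8% ± 1.0 to 23.5% ± 0.912 (SD, n = 2), with an adjusted limma-moderated p of 0.020. It overlaps no protein-coding gene. Windows overlapping Pak3 on the X chromosome (143700001 to 143800000), Epha5, an ephrin receptor gene, on chromosome 5 (84000001 to 84100000) and Dach2 on the X chromosome (113800001 to 113900000) fell to 15.9% ± 3.39, 18.9% ± 4.45 and 26.9% ± 1.87. Their control levels were 46.2% ± 6.13, 49.0% ± 7.71 and 56.8% ± 10.4 in that order. The fifth, on chromosome 3 (81700001 to 81800000), went from 47.8% ± 1.16 to 18.1% ± 5.39. These 5 windows held 56 to 365 calls per library. The greatest rise, from 27.1% ± 3.65 to 56.3% ± 4.64, was in a window of the X chromosome (104900001 to 105000000) in which the scaled coverage of the netrin-1 libraries was 3.71 times that of the controls. The other 4 rises were in a window overlapping Gabrg3, a GABA receptor subunit gene, on chromosome 7 (57200001 to 57300000), from 54.9% ± 0.133 to 74.0% ± 2.13, in one overlapping Usp32 on chromosome 11 (85000001 to 85100000), from 59.9% ± 0.176 to 71.3% ± 5.64, and in windows of chromosome 5 (26400001 to 26500000) and chromosome 7 (71900001 to 72000000).

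The number of windows called depended on how the dispersion was estimated and on single libraries, and differed when libraries were centred. Without the information minimum, which was set after counts had been seen, 348 windows were called, or 230 if the fit was also not robust, and 4 were called with neither trend nor robust fit. Unmoderated dispersion, limma on percentage points and limma on M values each called 0, with 1824, 4424 and 4420 windows at an unadjusted p under 0.05 against 5272 in the moderated test. With each library centred on its own mean, 0 windows were called and 2859 had an unadjusted p under 0.05. The count was 955 without control replicate 1, 19 without control replicate 2, 1221 without netrin-1 replicate 1 and 243 without netrin-1 replicate 2.

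CpG islands and their flanks were compared next. Islands were nearly unmethylated in both groups, at 2.76% ± 0.15 in control and 2.40% ± 0.110 in netrin-1 cells (SD, n = 2), a difference of -0.361 points over 14557 islands. Shores, the flanks next to islands, stood at 11.7% ± 0.149 and 10.6% ± 0.426, and shelves, the outer flanks, at 28.8% ± 0.0373 and 26.8% ± 0.923. The differences were -1.15 and -1.94 points, and the groups did not overlap in any of the 3 classes. Without netrin-1 replicate 2 the shelf difference was -1.29 points. The exact permutation p was 0.333 in each, the smallest possible. Among islands, those within genes were at 6.11% ± 0.428 and 5.29% ± 0.25, those at transcription start sites at 1.55% ± 0.0886 and 1.37% ± 0.0547, and those between genes at 4.23% ± 0.0697 and 3.51% ± 0.208. With the median in place of the mean the island difference was -0.0828 points and the shelf difference -3.05 points.

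Of 11815 CpG island features tested, 22 were called, 14 lower and 8 higher in netrin-1 cells. They are not all separate findings, since they have 17 nearest genes and some share sequence. Called shores overlap one another at Fat1, at Gm11770 and at Yam1. The greatest fall was in the island of Pdha2, which encodes the testis form of a pyruvate dehydrogenase subunit. This island (chromosome 3, 141211321 to 141211889, at the transcription start site) fell from 51.9% ± 5.12 to 8.71% ± 0.536 (SD, n = 2), with an adjusted limma-moderated p of 0.000909 and 89 to 440 calls per library. A shore of Ap1s3, an adaptor protein subunit gene, on chromosome 1 (79671938 to 79673937) fell from 55.7% ± 11.0 to 28.7% ± 1.71. A shore of St8sia1, a sialyltransferase gene, on chromosome 6 (142962032 to 142964031) fell from 23.0% ± 5.66 to 2.37% ± 1.20. A shore inside Fat1, an atypical cadherin gene, on chromosome 8 (44950827 to 44952826) fell from 38.5% ± 1.67 to 18.5% ± 1.21. The island at the start of Btbd18 on chromosome 2 (84658927 to 84659321) fell from 18.9% ± 5.56 to 3.4% ± 2.5. Other features that fell, chosen after their values were seen, were next to or inside Ywhag, Timm8a1 (13.1% ± 7.9 to 0% of 961 calls, which allows up to 0.312%), Spen, Prickle1, Ston2, Ptprt and Gm11770. The Prickle1 shelf lies on chromosome 15, whose coverage differed between the groups.

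Rises among CpG island features were mostly in features of very high coverage. The greatest, in a shelf near Lrrc8a on chromosome 2 (30233160 to 30235159), from 41.5% ± 11.1 to 75.8% ± 3.86, had 78 to 247 calls per library. The other features that rose had at least 4584. An intergenic shore and an overlapping island listed under Ccr1 on chromosome 9 (123923339 to 123925338 and 123924690 to 123925609) rose from 57.3% ± 0.376 to 68.0% ± 0.157 and from 60.03% ± 1.92 to 68.1% ± 0.106, on 4584 to 11162 calls per library. Islands listed under Mir5620 on chromosome 7 (7277785 to 7278551, overlapping Vmn2r29) and Gm21748 on the Y chromosome (90825141 to 90829322) rose from 56.9% ± 0.602 to 63.3% ± 2.18 and from 58.0% ± 1.67 to 63.2% ± 1.41. Features listed under Yam1 on chromosome 17, which include a copy of ribosomal RNA sequence, rose from 1.44% ± 0.209 to 2.06% ± 0.0408, from 1.56% ± 0.279 to 2.22% ± 0.18 and from 1.54% ± 0.208 to 2.29% ± 0.0182, on 84079 to 486752 calls. Such coverage can arise where reads from several copies of a sequence are placed at 1 locus, so these rises are uncertain. The count was 412 without the information minimum, 90 if the fit was also not robust, and 0 with unmoderated dispersion, limma on percentage points or limma on M values, where 432, 2252 and 2613 features had an unadjusted p under 0.05 against 1424 in the moderated test. With each library centred, 22 features were called, 7 lower and 15 higher, against 14 and 8. Without control replicate 1, control replicate 2 and netrin-1 replicate 1 the count was 132, 229 and 67.

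**Figure D3:**
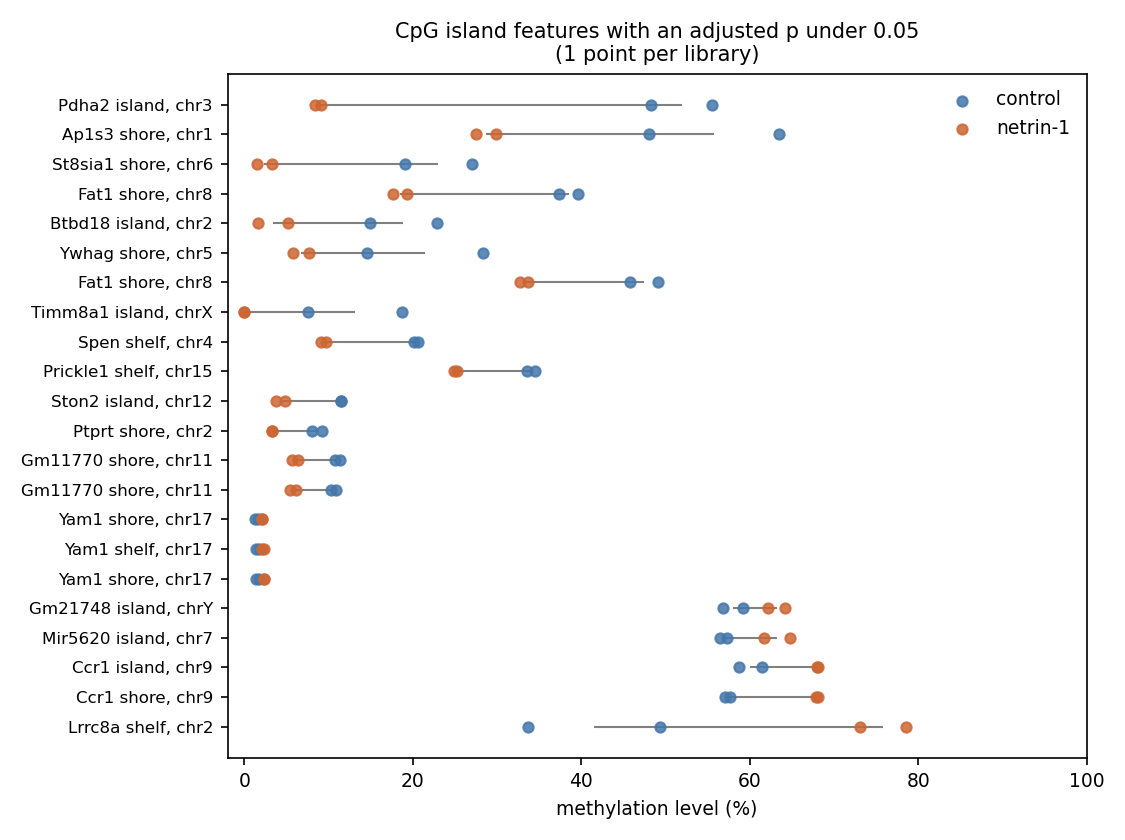
Methylation level in percent (horizontal axis) of the 22 CpG island features with an adjusted p under 0.05, 1 point per library and a line between the group means. Some of these features overlap. The Pdha2 island lies at about 8.71% in netrin-1 against 51.9% in control cells, and features with higher levels in netrin-1 cells are at the bottom.

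Genes were compared by promoter and body. Gene bodies stood at 29.0% ± 0.178 in control and 26.9% ± 1.12 in netrin-1 cells (SD, n = 2), a difference of -2.13 points over 19231 genes, or -1.34 points without netrin-1 replicate 2. Promoters stood at 7.20% ± 0.0518 and 6.46% ± 0.170, a difference of -0.739 points over 16527 genes. Promoters without a CpG island went from 21.3% ± 0.351 to 19.1% ± 0.494 between the groups, and promoters with one from 1.76% ± 0.0638 to 1.58% ± 0.0444. The groups did not overlap, and the exact permutation p was 0.333 for each class. The promoter difference was -0.421 points where at least 10 positions were covered, -0.320 points weighted by calls and -0.116 points as a median.

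Of 17209 gene features tested, 1 was called, the body of Pdha2 (chromosome 3, 141210004 to 141211855), which overlaps the island above. It fell from 49.8% ± 3.50 to 8.59% ± 0.560 (SD, n = 2), with an adjusted limma-moderated p of 0.0231 and 95 to 445 calls per library. None of 2068 tested promoters was called by the quasi-binomial test, and 255 of them, 232 lower, had an unadjusted p under 0.05. Among all gene features 2205 did. Limma on percentage points and on M values called 0 gene features, with 2311 and 2458 at an unadjusted p under 0.05. The test called 75 gene features without the information minimum, 11 if it was also not robust, and 0 without moderation, where 884 had an unadjusted p under 0.05. The count was 104 without control replicate 1, 52 without control replicate 2, 433 without netrin-1 replicate 1 and 20 without netrin-1 replicate 2. The promoters with the greatest non-overlapping differences had too few informative calls to be tested, 11 to 83 per library. Those higher in netrin-1 cells were Gm27506, at 20.5% ± 2.46 against 61.6% ± 7.17, and Gm13441, Mir322, Nat6 and Btnl10. Those lower were Itgb2, a leukocyte integrin gene, at 73.1% ± 14.4 against 33.6% ± 0.421, Rac2, a GTPase gene on chromosome 15, at 49.1% ± 11.4 against 9.21% ± 3.81, and Gm11755, Gm28374 and Gm14095.

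Ntn1 itself, the endogenous gene on chromosome 11, had a sparsely covered promoter (68400323 to 68401323) with 12 to 34 calls per library, at 2.94% ± 4.16 in control and 10% ± 14.1 in netrin-1 cells (SD, n = 2), and was not tested. Its body (68209364 to 68400323) stood at 26.8% ± 0.749 and 22.3% ± 3.03, with an adjusted limma-moderated p of 0.262 and so not called. The adjusted p was 0.0151 without netrin-1 replicate 1 and ran from there to 0.794 over the alternatives. Reads of the transgene were not separated from those of the gene. In the netrin pathway list, 18 of 22 measured promoters were lower and 4 higher, with a median difference of -0.537 points at percentile 0.94 of level-matched random lists. The camera adjusted p was 0.142. The promoter of Dcc, a netrin receptor, was at 10.7% ± 7.74 and 3.28% ± 0.978 and was the only 1 with enough information to test. It was not called over all genes tested (adjusted limma-moderated p of 0.212), and it was the 1 promoter called when adjusted over the list alone, where it had no other member beside it. Over all genes tested its adjusted p was 0.0179 without control replicate 1 and 0.0488 without netrin-1 replicate 1, and ran from 0.0179 to 0.765 over the alternatives. Mcam, which encodes a further netrin-1 binding protein, was at 1.80% ± 1.82 and 0.229% ± 0.324.

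Of the 11 gene lists, 1 passed camera at the preset correlation, the germline genes whose promoters are methylated in somatic cells. Of its 27 measured promoters 25 were lower and 2 higher, from a mean of 14.4% in control to 10.7% in netrin-1 cells, with a camera adjusted p of 0.00531. With an estimated correlation the adjusted camera p was 0.651, and fry gave an adjusted p of 0.501. The estimated correlation was -0.0103, below the preset 0.01, so a stronger correlation between promoters does not account for the loss. At a preset correlation camera takes promoters, not libraries, as its replicates. The camera adjusted p of 0.00531 is therefore not limited by the 2 libraries per group, while the p-values that did not pass are. The median difference of -2.93 points lay at percentile 13.98 of random lists of the same level, whose median was -1.64 points. Of the 18 promoters tested none was called over all genes tested, and 3 passed adjusted over the list alone. These, of which the first 2 were chosen after their values were seen, were D1Pas1, a testis helicase gene, at 8.14% ± 1.83 and 1.76% ± 0.717, Slc25a31, a testis nucleotide carrier gene in the chromosome 3 region of unequal coverage, at 15.4% ± 4.87 and 7.43% ± 1.83, and Tuba3b, a testis tubulin gene, at 23.5% ± 1.85 and 10.7% ± 2.27. Dpep3 was at 39.3% ± 4.88 and 29.7% ± 3.87, and Sycp1, a gene of the meiotic synaptonemal complex, at 30.8% ± 4.10 and 21.2% ± 22.3, with netrin-1 libraries far apart. The list's call was lost without control replicate 2 (adjusted p = 0.624) and without netrin-1 replicate 2 (adjusted p = 0.119).

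Pluripotency genes had lowly methylated promoters in both groups. Of 19 naive pluripotency promoters 13 were lower and 6 higher, with a median difference of -0.25 points and a camera adjusted p of 0.575. The most methylated of the named ones was Dppa3, a gene of naive and germ cells that lies in the chromosome 6 region of unequal coverage, at 27.8% ± 3.31 in control and 20.2% ± 3.77 in netrin-1 cells (SD over the 2 libraries). Prdm14 was at 3.91% ± 0.809 and 1.78% ± 0.954, and Tcl1 at 3.33% ± 4.71 and 0% of 165 calls, which allows up to 1.82%. Of 16 primed and formative promoters 4 were lower and 12 higher, with a median difference of 0.304 points at percentile 97.31 of matched lists and a camera adjusted p of 0.23. By fry's mixed test, which asks whether members change in either direction, the adjusted p was 0.0341. T, the brachyury gene, was at 3.43% ± 0.00378 and 0.368% ± 0.155, Lefty1 at 6.13% ± 3.85 and 9.47% ± 1.34, and Sox3 at 1.49% ± 0.463 and 4.66% ± 4.08. Only 1 of the naive and 2 of the primed promoters had enough information to be tested. Of these none was called over all genes tested or adjusted over the list alone.

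Imprinted genes had 26 of 33 promoters lower and 7 higher, with a median difference of -0.763 points at percentile 0.34 of matched lists and a camera adjusted p of 0.55. Plagl1 was at 12.4% ± 2.71 and 4.69% ± 1.31, Slc22a18 at 50.6% ± 7.95 and 41.7% ± 16.5, and Peg3 at 1.85% ± 2.62 and 8.88% ± 7.29. The DNA methylation machinery had 8 of 14 promoters lower, a median difference of -0.0620 points, a mean difference of 0.525 points and a camera direction upwards with an adjusted p of 0.575. Tet1, a gene for a 5-methylcytosine oxidase, was at 0% of 59 calls, which allows up to 5.08%, and 10.3% ± 6.45, Hells at 3.02% ± 1.43 and 0.872% ± 0.737, and Uhrf1 at 1.24% ± 0.999 and 2.90% ± 1.33. Wnt and MAPK targets had 12 of 25 promoters lower and 13 higher, with a camera adjusted p of 0.575. Lef1 was at 0.476% ± 0.673 and 2.91% ± 4.11, Spred2 at 2.19% ± 0.111 and 4.04% ± 2.60, and Spred1 at 1.58% ± 0.212 and 0.459% ± 0.142. Only 1 of the imprinted, 1 of the DNA methylation machinery and 2 of the Wnt and MAPK promoters could be tested, and none of these was called over all genes tested or adjusted over the list alone.

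Lineage genes did not pass either. The three-germ-layer list had 15 of 28 promoters lower (adjusted p = 0.55 by camera), the trophoblast list 8 of 12 (0.575) and the two-cell-like list 1 of 3 (0.33). Hoxb1 was at 12.2% ± 2.94 and 4.90% ± 2.71, and Hnf4a at 55.5% ± 11.9 and 47.3% ± 12.5. Of the trophoblast genes, Gata3 was at 7.42% ± 4.93 and 2.06% ± 0.665, Esx1 at 12.4% ± 6.23 and 5.67% ± 4.30, and Psg17 at 44.9% ± 33.2 and 19.7% ± 10.2. Of the two-cell-like genes, Pramel7 was at 42.8% ± 12 and 38.4% ± 13.3, Arg2 at 0.311% ± 0.440 and 1.63% ± 0.656, and Zfp809 at 0.347% ± 0.491 and 1.37% ± 1.28. The fibroblast list, which stands for another cell type the culture could hold, had 7 of 12 promoters lower and 5 higher and means of 15.7% in both groups (adjusted p = 0.623). Col1a1 was at 16.5% ± 19.7 and 28.2% ± 4.55, Col3a1 at 33.9% ± 11.4 and 27.9% ± 3.42, and Col6a1 at 100% ± 0 and 94.4% ± 7.86 on 11 to 18 calls. Only 2 three-germ-layer, 1 trophoblast, 1 two-cell-like and 2 fibroblast promoters could be tested, and none of these was called over all genes tested or adjusted over the list alone. Camera compares a list with the other promoters, and its direction was upwards for the Wnt and MAPK, three-germ-layer and fibroblast lists, where fry pointed downwards. The median and the mean differed in sign for the two-cell-like list, at 1.02 and -0.700 points.

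Coverage, counted as cytosine calls, differed between the groups in 42 of 532 bins of 5 Mb, with 1 sign in all 4 library pairs. Netrin-1 libraries had 1.61 times the coverage of the controls over chromosome 3 from 1 to 60000000 and 1.28 times over chromosome 6 from 120000001 to 140000000. On chromosome 3 the measured 1 Mb bins were higher in netrin-1 libraries up to 57000000. The 3 bins after that had log2 ratios of -0.16, -0.09 and -0.25, and every 5 Mb bin from 60000001 to 160000000 was lower in netrin-1 libraries in all 4 pairs. Netrin-1 libraries had 0.739 times over chromosome 13 from 25000001 to 50000000 and 0.723 times over chromosome 15. The methylation differences in these regions were -3.89, -3.10, -3.97 and -4.53 points, and outside them the window difference was -3.89 points.

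**Figure D4:**
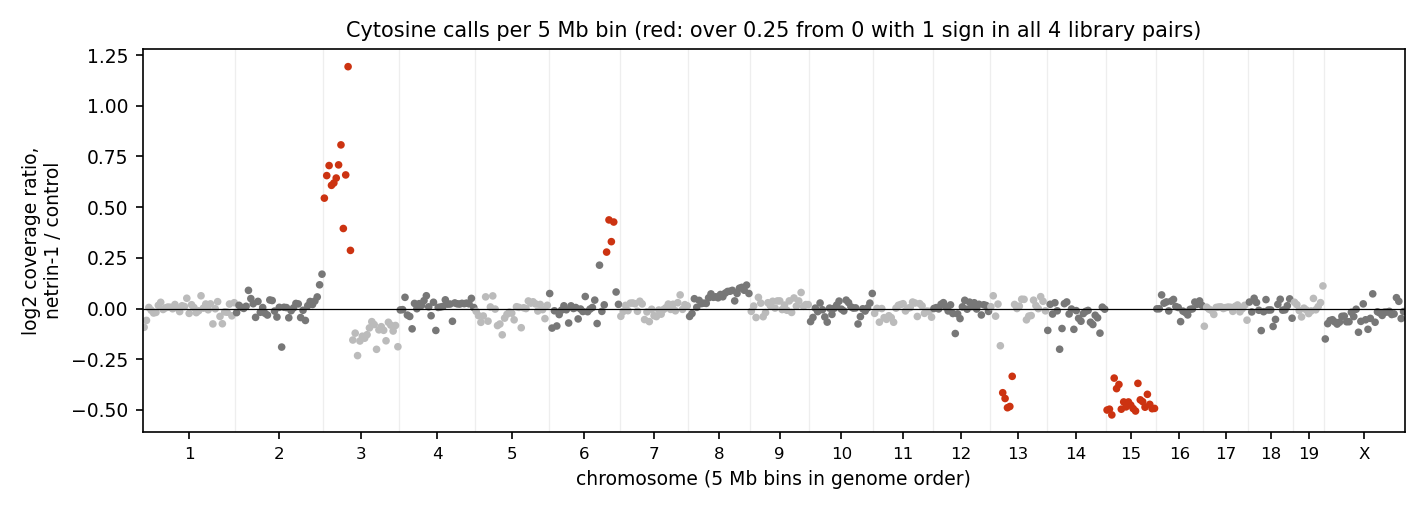
Log2 ratio of coverage, netrin-1 over control (vertical axis), in 5 Mb bins along the chromosomes (horizontal axis). Red points are the 42 of 532 bins set apart, which lie on chromosomes 3, 6, 13 and 15.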

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

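The tests of the conversion rate, of the regions of unequal coverage, of the divergence of the populations and of a single deviating library were chosen after the results they bear on had been seen. What drew attention was coverage, whose difference between the groups the methylation comparisons do not test. Coverage stood at 1.61 times the control level over chromosome 3 from 1 to 60000000, 1.28 times over chromosome 6 from 120000001 to 140000000, 0.739 times over chromosome 13 from 25000001 to 50000000 and 0.723 times over chromosome 15 from 1 to 105000000. The tests of single features use calls in their counts, filters and dispersion trend, so they are not independent of coverage.

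A difference in copy number between the 2 cell populations is a candidate explanation of these regions. Islands, which are partly other data than the windows, gave nearly the same log2 ratios, with a mean absolute gap of 0.0536 between islands and windows. This argues against fragment selection or GC bias, which would part the GC-rich islands from the windows (gap of 0.3 or more, against 0.0536 found). A single deviating library would leave some library pairs near a log2 ratio of 0, and is argued against too: in the 42 bins chosen by their mean ratio alone, the weakest pair was in median at 93.6% of the mean log2 ratio, and at 57.5% in the lowest bin. Copy number itself was not measured, so it stays a candidate. If it changed, it is also open when and in which cells this arose, and whether the transgene had any part in it.

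The lower methylation of the netrin-1 libraries was weighed as the second pattern. More complete bisulfite conversion would lower nearly unmethylated islands at least as much as windows. Islands picked for a mean level under 1% could not fall that far, so their difference of -0.00650 points does not decide this. All 14557 islands, not picked by level, stood at 2.76% in control and differed by -0.361 points, against -3.91 points in windows. At 2.76% they could not fall by as many points as the windows either. That level does cap what unconverted cytosines could add in the controls, and the cap is smaller than the window difference. The islands' own fall was smaller still. These values argue against conversion as the whole source of the window difference. Windows outside the regions of unequal coverage differed by -3.89 points, which argues against those regions as the cause of the mean difference. The count of single windows did change: without those bins 359 of 21841 tested windows were called, against 528 of 23743. Not all the lost calls lay in the regions. The whole of chromosomes 3, 6, 13 and 15 held 61, 36, 26 and 16 called windows, together fewer than the drop. Leaving bins out also changes the dispersion fit and the adjustment. Other CpG positions being covered stays open: the 359 windows whose number of covered positions differed by at most 2% between libraries differed by -4.86 points, but the tables give no positions, so equal numbers, which the test had taken as enough, do not show that the same ones were covered. The netrin-1 transgene and any other divergence of the 2 transfected populations cannot be told apart, because the labels give no independent populations per vector; the 2 controls differed by 1.67 points, which bounds only the spread within a label. The lower level may therefore follow the transgene, the history of the cells, the positions covered or other differences in preparing or sequencing the libraries. The labels name no batch, so this last point was not tested.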

How the results depend on the processing

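The tests with no moderation, with limma on percentage points, with no information minimum, not robust, and without bins of unequal coverage were chosen after the results were seen. All 72 mean differences, over 12 alternatives, were lower in netrin-1 cells, and 7 moved by at least 1 SD: weighted by calls to -2.83 (windows), -0.170 (islands) and -0.320 points (promoters), as medians to -0.0828 (islands), -3.05 (shelves) and -0.116 points (promoters), and with at least 10 covered positions to -0.421 points (promoters). With the replicate block a mean difference stays the same by construction. Leaving out 1 library could neither reverse it, since the groups did not overlap, nor move it by more than 1 SD. Only the other alternatives could change these means in that way. The counts of single features did not hold. In the order windows, CpG island features and gene features, 528, 22 and 1 became 0, 0 and 0 with limma on M values, limma on percentage points or no moderation; 4, 14 and 0 with no trend and not robust; 348, 412 and 75 with no information minimum; 230, 90 and 11 with none and not robust; and 1511, 34 and 299 with the replicate number as a block, though the numbers are not shown to pair the libraries. Without bins of unequal coverage the counts were 359, 19 and 1. Centring each library gave 0 windows. A mean level of 5 to 95% gave 5 CpG island and 5 gene features, at least 10 covered positions 71 and 5, and a difference of at least 10 points 11 CpG island features. Leaving out 1 library gave 19 to 1221 windows, 22 to 229 CpG island features and 20 to 433 gene features, with the lone sample of a group assumed to vary like the other group. The information minimum was set after counts had been seen. For windows the simulations gave little reason for it: recovery of falls of 20 points was 72 of 100 without and 71.3 with it, and false calls 6.67 and 6, while the real count went from 348 to 528, of which 338 were shared. For CpG island features mean simulated false calls went from 25 to 1, and with no robust step and no minimum they were 0.333. The cause of these changes was not tested.

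The germline list's adjusted p was 0.651 with an estimated correlation, 0.501 by fry, 0.326 with all features of the gene and 0.815 at a mean level of 5 to 95%, and 0.119 and 0.624 without netrin-1 replicate 2 and control replicate 2 (0.000434 to 0.624 leaving out 1 library), so that 0 lists passed in these cases. Directions reversed without passing for the Wnt and MAPK list (0.844 with all features, 0.961 by fry, 0.984 without control replicate 2, 0.903 without netrin-1 replicate 1, range 0.392 to 0.984), the fibroblast list (0.844, 0.961, 0.907 without control replicate 1, 0.893 without netrin-1 replicate 1), the three-germ-layer list (0.961 by fry), the naive list (0.893 without netrin-1 replicate 1, range 0.393 to 0.984) and the netrin pathway (0.815 at 5 to 95%). The 5 to 95% filter left 4 lists with no value. Pramel7 reversed without control replicate 1 (0.959) and netrin-1 replicate 2 (0.922; 0.46 to 0.959 leaving out 1 library), and Sycp1 without netrin-1 replicate 1 (0.691; 0.0557 to 0.840 leaving out 1 library). Calls were gained by Dcc and Tuba3b with the replicate block (0.0342 and 0.0289), by Dcc without control replicate 1 (0.0179) and netrin-1 replicate 1 (0.0488), and by the Ntn1 body without netrin-1 replicate 1 (0.0151). In simulations at the real coverage and levels, 0 of 100 falls of 10 points and 19 of 100 falls of 20 points were recovered among CpG island features of intermediate to high level. Falls of features at lower levels, where most islands lie, were not simulated. Depth itself was not varied.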

Other observations

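The test of gene content was written before its result was seen; the depth values were computed after the coverage ratios were known. At the same methylation level, windows without a protein-coding gene differed more between the groups than windows with one. At a level of 30 to 40%, 3041 windows without such a gene went from 38.0% ± 1.73 in control to 32.3% ± 0.231 in netrin-1 cells (SD, n = 2), a difference of -5.69 points, and 5598 windows with one from 37.2% ± 0.893 to 33.3% ± 1.01, a difference of -3.82 points. The gap was -1.79, -1.87 and -1.30 points in the bins from 20 to 30%, 30 to 40% and 40 to 50%. Its mean was -1.65 points, and it ran from -2.86 to -0.447 over the 4 library pairs, so its sign held in each but its size varied with the library. The pairs share libraries, so their agreement in sign is weak evidence. At 30 to 40% the SD of the controls was 1.73 without and 0.893 with a gene. That of the netrin-1 libraries was 0.231 and 1.01, so the gap also differed within each group. Of tested windows, 3.05% without and 1.79% with a protein-coding gene were called, a count that shares the dependence on the dispersion. Windows with a gene were more numerous and also differed, by -4.09, -3.82 and -3.06 points in the same 3 bins of level. Gene-poor windows held fewer calls, 905 against 1649 on average at 30 to 40%.

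Depth per covered position, relative to the median autosome of the same library, shows where each group stood against that median. Which group departed from its own baseline is not settled by it. A region may differ from the median in both groups, as chromosome 8 did. Chromosome 15 stood at 1.30 ± 0.0194 in control and 0.990 ± 0.000178 in netrin-1 cells, and the chromosome 13 region at 1.37 ± 0.0209 and 1.05 ± 0.000293, so in both the controls were above the median and the netrin-1 libraries near it. The chromosome 3 region stood at 1.20 ± 0.0358 and 1.86 ± 0.000626 and the chromosome 6 region at 1.01 ± 0.00505 and 1.26 ± 0.0175. Within chromosome 3, a run of 5 bins of 1 Mb from 51000001 to 56000000 reached 1.14 ± 0.00199 and 2.60 ± 0.00336, and holds 31 protein-coding genes, among them Foxo1, Smad9, Ccna1 and Dclk1, chosen after their positions were seen. Chromosome 8 was above the median in both groups, at 1.24 ± 0.00785 and 1.29 ± 0.0184, and the X chromosome below it in both, at 0.659 ± 0.0324 and 0.632 ± 0.0252. All are means ± SD over 2 libraries.

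Between the groups, the 4 libraries can be split into pairs in 3 ways. The real split called 528 windows, 22 CpG island features and 1 gene feature, and the highest count of the other splits was 0 in each table. Each of the other splits puts 1 control and 1 netrin-1 library on each side. A difference between the groups then adds to the spread within a side, so counts near 0 were largely fixed beforehand. These splits therefore give no null for the real counts, and they are too few for a share under 0.05.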
